A study of Cicer arietinum with 8 samples.

How the data were processed

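The study measured RNA from leaves of chickpea (Cicer arietinum) plants, described in the labels as leaves of 15 days, on 8 one-colour arrays. The labels name 4 groups of 2 arrays each: a control and plants given an agent written as Cr, Cd or As. The dose, the length of exposure and the form of each agent are not given in the sources used here. Nothing in the labels says whether the 2 arrays of a group came from separate plants, so the p-values below measure only the spread between these arrays, which may be technical.

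Per the labels' protocols, total RNA was reverse transcribed from an oligo-dT primer carrying a T7 promoter, copied into cRNA with Cy3-labelled CTP and, per the labels, measured on a custom chickpea array, whose probes in the files are 60 bases long. The deposited scanner files hold the intensity of each spot as read by Agilent Feature Extraction 11.5.1.1, per the file headers, with the spot's mean brightness and its local background beside the processed intensity. Per the file headers, the processed intensity had spatial and multiplicative detrending applied and no local background subtracted, and low values were replaced by a surrogate. The same deposited files give other columns, flags of 0 or 1, for spots well above background, saturated spots and outlier spots. The authors also deposited 1 log2 value per contig name and array. Set against the scanner values, these proved to be log2 signals less the array's 75th percentile over contig names, not centred by gene, with array medians between -2.42 and -2.24. For each of the contig names with 2 probes, the authors' log2 value matched the mean of the probes well above background on that array, or of both probes where neither was, to within 0.02 (log2).

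Each array carried 61657 non-control probes for 39613 contig names, of which 34379 start with TC and 5234 with Ca_MJ. The files give no description of any contig. None of the contig names matched the reference table of 29938 chickpea genes (0 matched), and no genome was used here, so contigs are reported by the names in the files, without a gene name or a position. The 36 gene lists that had been fixed by description before the data were examined therefore have 0 measured members, and the fallback rule for naming was used, read per comparison with the control: at most 2 contigs that rose and 2 that fell by the largest fitted log2 fold change, 1 probe per contig name (the one with the highest mean signal), past the threshold and with both treated arrays on the same side of both control arrays. The same numbers were named among contigs that changed the same way in all 3 comparisons, ranked by their smallest absolute log2 fold change. All 12 picks of the comparisons and the 4 shared ones lay at probes that were not well above background on either array of at least 1 group, so their sizes are given as lower bounds where that holds, and the ranking by fitted values is not a ranking by size. A second set of 12 and 4 contigs was therefore named by the same ranking with 1 more condition, that the probe be well above background on both arrays of the groups involved. This condition was added after the data had been seen, and 0 contigs are in both sets. Contigs that meet it are called bright below, although some lay at low signal in 1 group, where the fold depends on the background correction. As a substitute for the lists, probe sequences were translated in the 3 forward frames and searched for 50 families of short, conserved protein motifs. These families were set after the sequences were seen but before any comparison of groups. A probe found this way is described by its motif, which does not establish the gene it belongs to, and the motif probes given in full were chosen after their values were seen. Of the 50 families, 27 had at least 1 probe, 66 probes in all. The opposite strand gave 41 such probes and shuffled sequences gave 3. Of the forward hits, 65.2% were well above background on all 8 arrays, and of the opposite-strand hits 26.8%.

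For the comparisons, log2 processed signals had each array's 75th percentile over non-control probes subtracted, control spots and outlier-flagged spots were left out, and the 43207 probes well above background on both arrays of at least 1 group were kept. These belong to 32265 contig names. A linear model with a mean per group was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (4 residual degrees of freedom, variances moderated with an intensity trend), and p-values were adjusted per comparison by Benjamini-Hochberg with a threshold of 0.05. The differences between agents were tested in the same fit. Where a probe was below the well-above-background call on both arrays of one group, only a lower bound of the fold is given: the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the dim probe's own. The bounds refer to the processed signal, and folds after normexp, with 50 added to every signal, can be smaller. A reverse-complement probe under the same contig name is given as such and not as a second probe. Lists with at least 5 contigs were tested with limma's camera at a preset correlation of 0.01. The overlap of the responses was set against independent lists and against 20 simulations of unchanged groups sharing the control arrays, which were too few to split.

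The fit was tested on simulated data with the levels and spread of the 43207 probes and 4 sets of 50 probes changed in Cd minus Control. It recovered 30% of the 50 probes changed 1.5-fold, 46% of those changed 2-fold, 96% of those changed 4-fold and 96% of those changed 8-fold, and 14 of its 148 calls were unchanged probes. Far fewer probes changed there than passed in the comparisons below, which makes the adjusted threshold stricter. These shares therefore do not give the power of those comparisons. A simulated list of 16 probes shifted by 1 (log2) in As minus Control gave a camera p of 6.2e-38. The simulated probes varied independently and few others changed, so this p does not give the power of the list tests below.

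Between 61.8% and 69.2% of probes were well above background on each array, no probe was saturated, and the 75th percentile of the signal ran from 150 to 288. The number of arrays limits the precision. All 8 arrays lay on 1 slide and were scanned once. Control and Cr arrays lay on one side of the slide and Cd and As arrays on the other. Cr minus Control and Cd minus As are thus comparisons within a side, while in the other comparisons the side and the group cannot be told apart. Within a side, the 2 groups lay at different positions along the slide, so there the position and the group cannot be told apart. Replicate arrays correlated across probes at r = 0.984 or above, and arrays of different groups at 0.914 to 0.976.

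Before the data were examined, the alternatives chosen were normexp background correction (offset 50), quantile and median normalization, the authors' values, no filter and a stricter filter on dim probes, no intensity trend, the 2 compared groups alone, a replicate block, a position block, a minimum log2 fold change of 1 and leaving out each array. Scaling to the 8 E1A spike-in control probes detected in every group, centring on probe GC content, the second set of named contigs and the motif families were chosen after seeing the data.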

Results

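Gene expression in chickpea leaves was compared between control plants and plants given Cr, Cd or As, the symbols of chromium, cadmium and arsenic, with 2 arrays in each of the 4 groups. The comparisons ask which transcripts differ from the control under each agent and how far the 3 responses overlap. Arrays of the same group lay close together. The first principal component, with 49.9% of the variance, set the Cd arrays apart from the other 6, and the second, with 25.8%, set the As arrays apart. The median absolute difference between replicates was 0.10 (log2) in the control, 0.07 in Cr, 0.14 in Cd and 0.23 in As. The 100 brightest probes held 27.8% to 28.0% of all signal on the control arrays, 27.2% to 27.9% on the Cr arrays, 27.3% to 29.0% on the As arrays, and 19.7% to 21.2% on the Cd arrays.

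**Figure D1:**
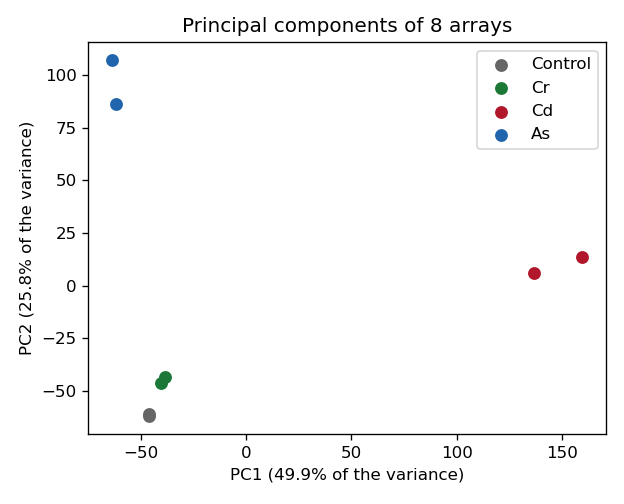
Scores of the 8 arrays on the first 2 principal components of the log2 signals less the 75th percentile, 1 point per array, coloured by group. The Cd arrays lie apart on the first component (49.9% of the variance) and the As arrays on the second (25.8%), while the Cr arrays lie nearest to the controls.

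In Cr-treated leaves, the contigs ranked first by fitted log2 fold change were bright in one group and not well above background in the other. The fitted fold is not a size for such probes, so bounds are given, which hold for the processed signal and not under normexp background correction, and the ranking is not one of size. Ca_MJ0199374 was at least 34.1-fold higher than in the control (log2 signal 0.30 ± 0.02 in Cr, SD, n = 2) and TC31807 at least 20.3-fold higher. TC23479 was at least 9.8-fold lower and TC17396 at least 7.68-fold lower, while the reverse-complement probe of TC17396 had a log2 fold change of -0.54. Their adjusted p (limma) was 0.00119 or below. With normexp, where an offset of 50 added to every signal shrinks the folds of dim probes, the log2 fold changes were 2.20 for Ca_MJ0199374, 1.88 for TC31807, -1.22 for TC23479 and -0.88 for TC17396. By bound, TC24564 (29.8-fold higher) and TC04791 (23.3-fold higher) lay above TC31807 but below Ca_MJ0199374, and TC28463 and TC11561, given next, fell by more than the bounds of TC23479 and TC17396. All 21 bounded values of the contigs named by this ranking, here and below, lay under their bounds with normexp. The probe of Ca_MJ0199374 has the sequence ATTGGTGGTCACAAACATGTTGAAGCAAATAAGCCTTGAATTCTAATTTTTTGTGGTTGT.

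Among contigs bright in both groups, a condition added after the data had been seen, TC11040 rose 19.9-fold over the control in Cr (log2 2.97 ± 0.04 against -1.34 ± 0.01, SD, n = 2 each), and a second probe of the contig gave a log2 fold change of 4.62. TC22887 rose 17.4-fold from a low control signal of -4.36 (log2), and by log2 1.71 with normexp. The name of its probe holds the letters Xhyb, which the sources used here do not explain. TC28463 fell (log2 fold change -4.32 ± 0.19, SE) and TC11561 fell 16.6-fold, the latter from 4.40 ± 0.12 to 0.34 ± 0.04, with a second probe at -4.34. The adjusted p of these contigs (limma) was 1.09e-05 or below. The probe of TC11040 has the sequence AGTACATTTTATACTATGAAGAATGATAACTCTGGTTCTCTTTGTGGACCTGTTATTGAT and that of TC11561 the sequence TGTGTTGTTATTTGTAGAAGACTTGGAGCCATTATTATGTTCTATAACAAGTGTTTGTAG. TC11040 also rose in Cd and As, by log2 2.46 ± 0.13 (SE) and 3.80 ± 0.13. TC11561 did not pass the threshold in Cd (-0.25 ± 0.13, adjusted p = 0.144) or As (-0.19 ± 0.13, adjusted p = 0.281), and it was lower in Cr than in either (Cr minus Cd -3.80, Cr minus As -3.86).

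Across the array, 7485 of 43207 probes (17.3%), from 6610 contig names, passed the threshold in Cr minus Control, 3659 higher and 3826 lower. The fitted fold was at least 2 in 1118 higher and 1166 lower, of which 742 and 887 were well above background on all arrays of both groups; 117 and 113 more had a bound of at least 2-fold. Of the 7485, 243 were bright in Cr and not well above background in the control, 11 of them by a bound of at least 8-fold, and 198 were in the opposite state, 3 of them by at least 8-fold. The count moved with the arrays in the fit. It was 17505 when only these 2 groups were fitted, 12163 without either As array, and between 2908 and 3266 without a Control or Cr array (2908 without Cr replicate 2, 3017 without Cr replicate 1, 3184 without Control replicate 1 and 3266 without Control replicate 2). Scaled to the spike-in probes, 15291 probes were higher and 1768 lower, and by a fitted fold of at least 2 3017 and 609. Under that scaling the median log2 fold change of all tested probes was 0.37, against 0.02 with the 75th percentile.

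Under Cd, TC17514 was at least 91.9-fold higher than in the control, where it was not well above background (log2 signal 1.73 ± 0.13 in Cd, SD, n = 2), and TC12413 at least 49.9-fold higher, with a second probe of that contig at a log2 fold change of 6.37. TC17080 was at least 37.3-fold lower and TC32736 at least 33.7-fold lower, neither being well above background in Cd. Their adjusted p (limma) was 5.59e-07 or below. With normexp the log2 fold changes were 3.71, 2.92, -2.88 and -2.66 in this order. By bound, TC03168 (62.0-fold higher), TC04791 (59.7-fold higher) and TC06530 (53.5-fold higher) were among the contigs above TC12413. TC18723 (42.9-fold lower) and a second probe of TC02741 (38.1-fold lower) lay above TC17080. The probe of TC17514 reads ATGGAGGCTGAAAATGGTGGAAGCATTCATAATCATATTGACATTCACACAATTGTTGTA and that of TC17080 reads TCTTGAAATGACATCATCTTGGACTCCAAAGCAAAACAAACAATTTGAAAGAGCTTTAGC. In Cr and As, TC17514 did not pass the threshold against the control (adjusted p = 0.59 and 0.908), and it was lower in both than in Cd (adjusted p = 4.64e-07 and 4.74e-07).

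Among contigs bright in both groups, the fitted rise of TC17486 in Cd was 229-fold (log2 3.91 ± 0.02 against -3.94 ± 0.17, SD, n = 2 each) and that of TC17109 134-fold. Their control signals, -3.94 and -4.21, were low though well above background. With normexp their log2 fold changes were 5.55 and 4.60, against 7.84 and 7.06 without it. TC02741 fell 105-fold, from 5.34 ± 0.09 to -1.37 ± 0.13, and TC15296 fell 81.7-fold. Their adjusted p (limma) was 2.02e-08 or below. A second probe of TC15296 had a fitted log2 fold change of -6.84. The second probe of TC02741 was not well above background in Cd and was at least 38.1-fold lower there than in the control. The probe of TC17486 reads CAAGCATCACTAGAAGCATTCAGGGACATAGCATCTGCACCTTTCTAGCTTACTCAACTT and that of TC02741 reads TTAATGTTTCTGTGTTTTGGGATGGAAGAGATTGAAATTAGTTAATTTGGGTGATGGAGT. TC17486 was also higher in Cd than in Cr (adjusted p = 3.05e-08) and than in As (adjusted p = 9.23e-09). TC15296 was lower in Cd than in As (Cd minus As -6.49 ± 0.09), and its As level did not differ past the threshold from the control (0.14 ± 0.09, adjusted p = 0.261).

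In Cd minus Control, 21128 probes (48.9%), from 17424 contig names, passed the threshold, 8607 higher and 12521 lower. The fitted fold was at least 2 in 3842 higher and 5098 lower, of which 2745 and 3744 were well above background on all arrays of both groups, and at least 8 in 612 and 207, of which 210 and 113 were, or 333 and 131 with those that had a bound of at least 8-fold. Of the 21128, 832 were bright in Cd and not well above background in the control, 586 of them by a bound of at least 2-fold, and 681 were in the opposite state, 331 of them by at least 2-fold. Fitted on the Cd and Control arrays alone, 22739 probes passed, and 23470 did with the position along the slide, which these arrays share, as a block. The direction of the split depended on the scaling. Spike-in scaling gave 24682 higher and 2983 lower (12380 and 1141 by a fitted fold of at least 2) and moved the median log2 fold change from -0.14 to 0.63, and normexp background correction gave 7978 higher and 22327 lower with a median of -0.23.

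Under As, Ca_MJ0199374, the contig named first for Cr, was at least 340-fold higher than in the control (log2 signal 3.62 ± 0.08 in As, SD, n = 2) and TC25892 at least 203-fold higher, neither being well above background in the control. TC01478 was at least 26.2-fold lower and Ca_MJ0024820 at least 10.6-fold lower, and neither was well above background in As. Their adjusted p (limma) was 5.04e-06 or below. With normexp the log2 fold changes were 5.23, 4.51, -2.14 and -1.29 in this order. By bound, TC15822 (16.5-fold lower) lay above Ca_MJ0024820. The probe of TC25892 reads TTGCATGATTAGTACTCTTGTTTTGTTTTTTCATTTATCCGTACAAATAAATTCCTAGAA and that of TC01478 reads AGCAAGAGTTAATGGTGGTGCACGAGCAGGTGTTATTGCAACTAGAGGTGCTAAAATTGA. Ca_MJ0199374 was higher in As than in Cr (Cr minus As -3.32 ± 0.13, SE) and than in Cd (Cd minus As -3.71 ± 0.13). TC01478 also fell in Cr (-2.82 ± 0.11) but rose in Cd (3.37 ± 0.11).

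Among contigs bright in both groups, TC14507 rose 49.2-fold in As (log2 2.84 ± 0.29 against -2.78 ± 0.34, SD, n = 2 each; a second probe at log2 fold change 7.47) and TC17125 rose 41.3-fold (reverse-complement probe 4.76). TC13800 fell 20.8-fold (log2 -2.13 with normexp) and TC04792 fell 12.9-fold (second probe -3.96). Their adjusted p (limma) was 1.83e-06 or below. The probe of TC14507 reads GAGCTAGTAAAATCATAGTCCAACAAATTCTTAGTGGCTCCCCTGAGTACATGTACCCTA and that of TC04792 reads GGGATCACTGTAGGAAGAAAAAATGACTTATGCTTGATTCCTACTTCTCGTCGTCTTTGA. TC13800 moved in opposite directions under As and Cd: it was -4.38 ± 0.23 (log2 fold change, SE) in As and 2.16 ± 0.23 in Cd, a difference of 6.54 between the agents (adjusted p = 7.06e-08).

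In As minus Control, 17177 probes (39.8%), from 14545 contig names, passed the threshold, 8512 higher and 8665 lower. The fitted fold was at least 2 in 2661 higher and 3547 lower, of which 2083 and 1997 were well above background on all arrays of both groups. Of the 17177, 1163 were bright in the control and not well above background in As, 310 of them by a bound of at least 2-fold, against 274 in the opposite state, 224 by at least 2-fold and 20 by at least 8-fold. The count was 11129 without Control replicate 1 and 11330 without Control replicate 2. Fitted on the As and Control arrays alone it was 13681, below the 17505 of Cr minus Control fitted in the same way. With spike-in scaling, 2310 probes were higher and 27352 lower (928 and 12823 by a fitted fold of at least 2), with a median log2 fold change of -0.70 against -0.03, and normexp gave 13436 higher and 6717 lower with a median of 0.10.

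**Figure D2:**
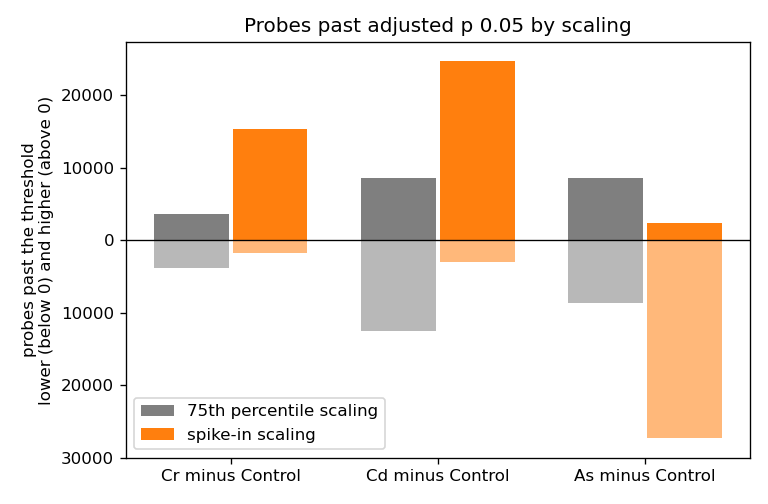
Probes past an adjusted p of 0.05 in each comparison with the control, higher above 0 and lower below 0, with the 75th percentile scaling (grey) and the spike-in scaling (orange). The split in Cr is 3659 higher and 3826 lower with the first and 15291 and 1768 with the second, and in As it goes from 8512 and 8665 to 2310 and 27352.

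**Figure D3:**
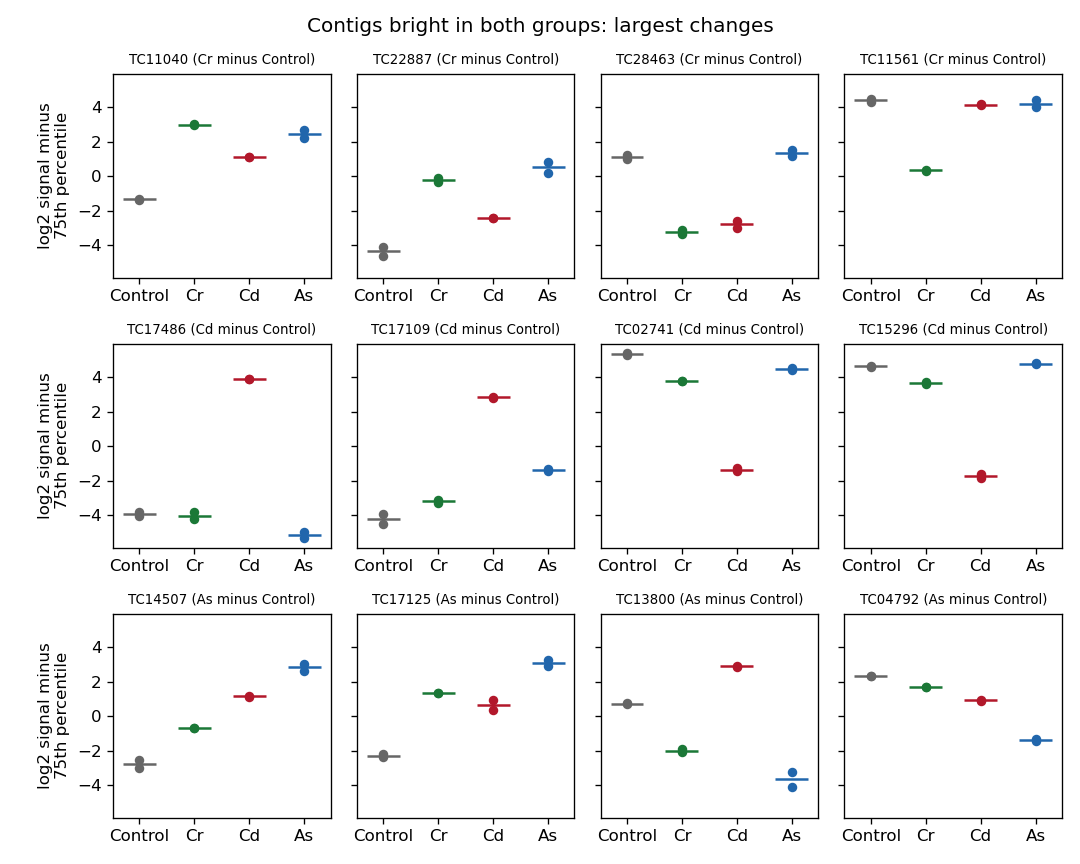
Log2 signal less the array's 75th percentile of the 12 contigs bright in both groups named for Cr, Cd and As, 1 point per array with the group mean as a line, 2 arrays per group. TC17486 lies at 3.91 in Cd and at -3.94 in the control, and TC11561 lies at 0.34 in Cr and at 4.40 in the control.

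The agents also differed from one another. Cr and Cd differed in 20903 probes, with 12382 higher in Cr and 8521 lower. Cr and As differed in 18197 probes, 9243 higher in Cr and 8954 lower, and Cd and As in 25175, 10907 higher in Cd and 14268 lower. Of these, only Cd minus As lies within 1 side of the slide, where the 2 groups lay at different positions along it. With spike-in scaling the splits were 5813 higher and 16759 lower in Cr minus Cd and 35303 and 1125 in Cd minus As, both turned, and 34490 and 930 in Cr minus As, the same way but far more uneven. Normexp gave 21883 and 8211 in Cr minus Cd, 7118 and 15409 in Cr minus As, and 7999 and 25299 in Cd minus As, and median scaling gave 6676 and 10957 for Cr minus As. Probes that differed from the control and from both other agents in one direction numbered 731 higher and 1228 lower in Cr, 4514 higher and 7505 lower in Cd, and 4454 higher and 4210 lower in As. Leaving out Cr replicate 2 lowered the Cr minus Cd count to 13913 and the Cr minus As count to 11064, and leaving out Cr replicate 1 lowered the Cr minus As count to 11251.

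Some contigs changed the same way under all 3 agents. Ca_MJ0199374 was at least 34.1-fold higher in Cr, 26.0-fold in Cd and 340-fold in As than in the control, and TC06530 at least 21.4-fold, 53.5-fold and 25.4-fold. TC10343 was at least 6.07-fold lower in Cr, 6.51-fold in Cd and 4.08-fold in As. TC19548 was lower by at least 4.52 (log2) in Cr and at least 24.6-fold lower in Cd, and in As, where 1 of 2 arrays was well above background, its log2 fold change was -4.01 ± 0.39 (SE). Their adjusted p (limma) was 0.000166 or below. With normexp the log2 fold changes in Cr, Cd and As were 2.20, 1.84 and 5.23 for Ca_MJ0199374, 1.96, 3.09 and 2.10 for TC06530, -0.88, -1.24 and -0.65 for TC10343, and -1.85, -2.33 and -1.53 for TC19548. Among contigs bright in all groups, TC12572 rose by log2 3.80 in Cr, 4.78 in Cd and 4.17 in As (SE 0.14), and Ca_MJ0237159 by 3.55, 5.54 and 3.59 (SE 0.14). TC18304 fell in each, with log2 fold changes of -3.10, -3.64 and -2.65 (SE 0.29), and TC21907 with -2.46, -5.11 and -2.34 (SE 0.08), at an adjusted p of 0.000155 or below. With normexp, in the same order of agents, TC12572 had 2.48, 3.40 and 2.81 and Ca_MJ0237159 had 1.52, 3.20 and 1.55. TC18304 had -1.84, -2.21 and -1.50 with normexp, and TC21907 had -2.32, -4.56 and -2.33. In all, 1490 probes were higher and 640 lower past the threshold in the 3 comparisons, where independent lists of the same lengths would share 144 and 222. The pairs shared 2087 higher and 1658 lower probes for Cr and Cd (729 and 1109 for independent lists), 2154 and 1552 for Cr and As (721 and 767), and 3143 and 3058 for Cd and As (1696 and 2511). The number in all 3 fell to 1056 without Cr replicate 2, 1059 without Cr replicate 1, 1091 without Control replicate 1 and 1111 without Control replicate 2.

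The 3 comparisons share the 2 control arrays, so part of the excess may come from them. The Cd and As arrays also lay on the other side of the slide from the controls. An effect of the side would enter both of their comparisons and could add to their overlap and covariance, and it cannot be told apart here. Simulated unchanged groups sharing the controls gave at most 1 probe called the same way in a pair and 0 in all 3. Without changed probes almost nothing is called, so these counts cannot show how much of the overlap the shared controls give. The simulations hold only the spread between arrays, so they leave out a deviation that both control arrays share. Fold changes correlated across probes, which are not independent replicates, at r = 0.35 for Cr and Cd, 0.43 for Cr and As and 0.30 for Cd and As, below the simulated 0.50 that shared controls give without effects. The covariance was 0.21, 0.20 and 0.24 in the same order, against a simulated 0.03 in each, a difference of 0.17, 0.16 and 0.21. Opposite calls numbered 1398 for Cr and Cd, 1318 for Cr and As and 3944 for Cd and As, against 1823, 1488 and 4193 for independent lists.

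Among the 57 tested probes that carry a protein motif, 4 were higher and 11 lower past the threshold in Cr, 15 higher and 20 lower in Cd, and 14 higher and 22 lower in As. The probes named here were chosen after their values were seen. Of the 86 values past the threshold, 79 were smaller with normexp. A probe with MDCEGC, the metal-binding loop of heavy-metal-associated proteins, moved in opposite directions. It was higher in Cd by log2 2.97 ± 0.20 (SE, adjusted p = 3.47e-06). In As it was not well above background, at least 4.28-fold below the control (adjusted p = 1.15e-06, log2 -0.53 with normexp). In Cr it was lower past the threshold (-0.68, and -0.28 with normexp). The family's probe with MHCDGC had values of the other sign, -0.82 ± 0.29 in Cd (adjusted p = 0.0396) and 1.24 ± 0.29 in As (adjusted p = 0.0075). With spike-in scaling neither passed the threshold (-0.058 and 0.57), and the Cd value did not with median scaling or quantile normalization. The signs were kept, with -0.49 and 0.52 under normexp, but whether this probe changed depends on the scaling. Probes with the haem-binding loop of cytochrome P450 enzymes also parted: FGLGRRACPG was higher by 2.27 ± 0.28 in Cd and lower in As (-1.49 ± 0.28, adjusted p = 0.00233), where 1 of 2 arrays was well above background and normexp left it not past the threshold. FGFGRRGCPG and FGAGRRMCPG were lower in As (-1.11 ± 0.12 and -1.09 ± 0.09), with the reverse-complement probe of the former at -0.27. Both were also lower past the threshold in Cr (-0.60 and -0.69). FGAGRRMCPG was 0.25 in Cd (adjusted p = 0.0363), not past the threshold with median scaling. The probe with HCGWNS, the sugar-donor-binding box of plant glycosyltransferases, was higher in Cd (2.04 ± 0.13) and in As (1.25 ± 0.13). A probe with LSGAHTIG, a motif of secreted plant peroxidases, was higher in Cd by 2.18 ± 0.31 and in As by 0.88 (0.37 with normexp in As). The WRKY transcription factor heptad WRKYGQK was lower in As (-1.26 ± 0.26, adjusted p = 0.00429, -0.19 with normexp). Its Cd value was not past the threshold, but it passed at 0.67 with spike-in scaling and at -0.23 with normexp, so a change in As alone is not shown. With normexp the other values were 1.96 for MDCEGC, 1.15 for FGLGRRACPG, 1.27 for HCGWNS and 0.48 for LSGAHTIG in Cd, and 0.73 for HCGWNS in As. The TIFY motif of jasmonate repressors and relatives, LTIFYGG, was lower in As (-1.28 ± 0.08, second probe -1.05) and in Cd (-0.39 ± 0.08, second probe -0.28), where spike-in scaling turned the direction to 0.38.

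In Cd, a probe with HPNINSNGNIC, from ubiquitin-conjugating enzymes, was lower by log2 fold change -1.82 ± 0.09 (SE), and one with GTSMACPH, from subtilisin-like proteases, by -2.07 ± 0.10 (reverse-complement probe -1.46). Both were also lower past the threshold in As, by less (-0.49 and -0.52). The probe with QVWPPI, in the family of photosynthetic proteins, was lower in Cd (-1.11 ± 0.11, reverse-complement probe -1.10), but by -0.20 with quantile normalization and -0.34 with spike-in scaling. Its direction in As was not settled: 0.37 ± 0.11 (adjusted p = 0.0265), 0.058 with quantile normalization (adjusted p = 0.555) and -0.30 with spike-in scaling. A probe with QGQCGSCWAF, the active site of papain-like proteases, was higher in Cr (1.76 ± 0.08, second probe 0.89). It was also higher past the threshold in Cd (0.50) and As (0.59), but its As value turned direction with spike-in scaling.

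The protein kinase family was the only motif list with at least 5 contigs. Of its 16 tested contigs, 2 were higher and 4 lower past the threshold in Cr, 5 higher and 4 lower in Cd, and 4 higher and 6 lower in As. Adjusted over the list alone, the counts were 2 and 6, 5 and 4, and 4 and 7. Against other contigs, the list as a whole did not pass the threshold in any of the 3 comparisons (camera, adjusted p = 0.313 in each, and 0.537 with an estimated correlation). Its members moved apart: the probe with HRDIKPSNL was 2.26 ± 0.21 higher in Cd, but a second probe of its contig went the other way (-0.73), so the direction of that contig is open, and normexp gave 0.78. The probe with HRDLKSENL was 1.83 ± 0.14 higher in As (second probe 1.84). That with GTTGYLAPE was 1.85 ± 0.16 higher in Cd and 2.03 ± 0.16 in As (second probe 1.43 and 2.12, normexp 0.83 and 1.01). The probes with HRDLKSENL and GTTGYLAPE were also higher past the threshold in Cr (0.71 and 0.65). That with GTVGYMDPE was lower in Cr (-1.82 ± 0.14) and higher in Cd (0.84 ± 0.14, adjusted p = 0.00102).

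Separate probes of 1 contig moved together. For 6930 contig names with 2 probes well above background on all 8 arrays, the log2 fold changes of the probes correlated across contigs at r = 0.74 in Cr, 0.84 in Cd and 0.79 in As. Where both probes passed the threshold, they had the same direction in 720 of 725 contigs in Cr, 2586 of 2653 in Cd and 2033 of 2059 in As.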

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

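Control probes outside the comparisons gave signal above that of the negative controls, of whose spots 0.69% were well above background. Of the spots of the 12 ERCC control probes, 22.4% were well above background, and of those of the 13 ETG control probes, 14.4%. Whether RNA for these probes was added is not given in the sources used here. ERCC-00104_60 was well above background in 100% of its spots on each of the 8 arrays. ETG10_236652 was well above background in 100% of its spots on 7 of the arrays, with a mean log2 signal of 8.39 on Cd replicate 1, and in 0% on Cd replicate 2, where its mean log2 signal was 2.31. ERCC-00028_121 showed the same gap, with 94.3% of its spots on Cd replicate 1 and 2.86% on Cd replicate 2, at mean log2 signals of 4.45 and 1.68. These single probes were chosen after their values were seen, and no explanation was tested.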

How the results depend on the processing

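Spike-in scaling and GC-centring were chosen after seeing the data, the other settings before. Of the 2382 values of named contigs and motif probes under other settings, 2188 kept their direction and call, 182 were no longer past the threshold and 12 turned direction. The 386 values of the contigs named by the rule and the 446 of those bright in both groups kept direction and call, so that each exception was a motif probe. The named contigs were picked from these same arrays as the largest changes past the threshold, which made keeping the call likely from the start. The sizes were not kept with normexp, whose offset of 50 shrinks folds of dim probes by construction. All 22 values by the rule and all 24 of the bright set were smaller, as were 79 of the 86 motif values (down to 0.0083 times the log2 fold change). All 21 bounds were undercut (Ca_MJ0199374 2.20 in Cr against a fitted 7.01). Arrays sharing a replicate number did not deviate together (r across probes of deviations between -0.09 and 0.05), so the numbers do not pair the arrays. A replicate block changed no count by over 1.5 times: it gave 6991 calls in Cr minus Control, 20773 in Cd minus Control, 16773 in As minus Control and 1996 probes shared by all 3. Signal near background limits what dim probes show, and the rule's contigs are such probes in at least 1 group. The mean of all probes per gene was not run, nor were the lists by description, as no gene names were to be had. A position block could be fitted only where 2 groups share positions, and was fitted on those 2 groups alone. It gave 23470 in Cd minus Control, against 22739 without the block, and 17282 in Cr minus As, against 15007. No block for the side of the slide could be fitted.

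Requiring a fitted log2 fold change of at least 1, which is no size for probes near background, left, by construction, 2284 calls in Cr minus Control, 8940 in Cd minus Control, 6208 in As minus Control, 9041 in Cr minus Cd, 6092 in Cr minus As, 11922 in Cd minus As and 746 shared by all 3. The authors' values, over the 15799 contigs with 1 probe only, gave 3495, 8470, 7059, 8364, 7356, 9703 and 1004 in that order, where the signals of the same probes gave 3431 in Cr minus Control. Spike-in scaling gave 17059 in Cr minus Control, 29662 in As minus Control and 35420 in Cr minus As. Fitting the 2 groups alone gave 17505 in Cr minus Control and 13681 in As minus Control, so Cr then had more calls than As. The order of these counts thus depends on the arrays in the fit. The causes of these shifts were not tested.

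Leaving out 1 array, where the lone array of its group is assumed to vary like the other groups, gave 2908 to 12163 calls in Cr minus Control, 14623 to 25162 in Cd minus Control, 11129 to 20546 in As minus Control, 13913 to 24786 in Cr minus Cd, 11064 to 21557 in Cr minus As, 20978 to 26130 in Cd minus As and 1056 to 3052 shared by all 3.

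With spike-in scaling the motif probes that turned direction, with the cause not tested, were in Cd TIFY (0.38), a kinase (0.44), a small GTPase (0.33), an aquaporin (0.54), and ubiquitin-related probes (0.24 and 0.32), and in As kinases (-0.32 and -0.080), photosynthesis (-0.30), a papain-like protease (-0.081) and a GDSL lipase (-0.020). With quantile normalization the aquaporin probe turned in Cd (0.15).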

Other observations

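Of the tests below, those of scanner compression, of the slide side and of labelling on the antisense strand were chosen after the result they bear on was seen, and spike-in scaling and GC-centring after seeing the data. Probes not well above background on both control arrays, and called higher with a bound in all 3 agents, numbered 109, of which 63 had a bound of at least 2-fold in each. Among them TC04791, chosen after its values were seen, was at least 23.3-fold higher in Cr, 59.7-fold in Cd and 58.4-fold in As.

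The brightest leaf probes were lower in Cd relative to the rest. Of the 616 probes in the top 1% on the Cr arrays, 479 were called lower and 34 higher in Cd, with a median log2 difference of -0.80 (quartiles -1.20 and -0.33), and 95 were lower and 276 higher in As. The E1A spike-in probes argue against scanner compression, since the 3 brightest moved by 0.085 (log2, Cd minus Control) against 3 of middle brightness. The As arrays, on the same side of the slide, had these probes at a median of 0.27, but at -0.40 with spike-in scaling. The sign depends on the scaling and As may itself change these probes, so an effect of the side is not decided. Centring on GC content left the Cd median at -0.83. With spike-in scaling the Cd median was -0.04, so the probes are lower relative to other probes and not on every scale; a response of abundant leaf transcripts to Cd stays a hypothesis.

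Of the 11878 probes with names ending in nh, letters not explained in the sources used here, 699 (5.9%) were well above background on all 8 arrays. Of probes ending in h, 82.5% were. These 699 had a median log2 difference of -0.53 in Cd, and 237 were called lower and 29 higher. Probes with names ending in h and matched on the signal of the Cr and As arrays had a median of -0.06, a gap of -0.47, which argues against low signal. The gap was -0.46 after centring on GC content. In As these 699 nh probes had a median of 0.071, while the 2694 tested nh probes had -0.12, with 124 called higher and 378 lower. The As values therefore do not decide whether the slide side has a part. With spike-in scaling the Cd median was 0.23, so that these probes, too, are lower only relative to others. A lower median in Cd was not particular to nh. Among probes well above background on all 8 arrays, it was -0.23 for names ending in ST, -0.23 for AS and -0.21 for S, against -0.08 for h, not matched on signal. What the nh probes have in common may be a class of transcript, which could not be tested without an annotation.

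The array held 7155 pairs of exact reverse-complement probes under 1 contig name, and in 928 both strands were well above background on all arrays, against 1873 and 1553 with only 1 of them and 2801 with neither. Antisense copied from the sense transcript during labelling would make both strands move together as separate probes of a contig did (r = 0.74 in Cr, 0.84 in Cd and 0.79 in As), but the strands correlated at r = 0.31, 0.21 and 0.42. Of the pairs with both strands called, 2 of 28 went opposite ways in Cr, 79 of 340 in Cd (0.69 times the number from chance pairing of the calls) and 14 of 127 in As, where chance pairing gives 14.4, 115 and 63.4. The strands thus moved the same way more often than unlinked calls would, most clearly in Cr and As. A copied share of the signal or shared regulation of the strands would both do this, and the values do not tell them apart.

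The criterion of the antisense test replaced an earlier one, set on levels, because the brighter and dimmer of any 2 values correlate by construction (r = 0.44, and 0.45 with the pairs shuffled), and the new criterion was written with the fold-change correlations already seen. The limit of the chance-pairing test, 2 times the chance number, was written before the count, but the value that would have counted against it was completed afterwards.

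In the authors' deposited values, the probes behind a contig name can differ between arrays. Of 19446 contig names with 2 probes, 6774 changed in this way over the 8 arrays. In As minus Control, 791 of these had a difference of at least 2-fold in the authors' values with neither probe differing by as much, as had 611 in Cd and 587 in Cr.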
